A study of Caenorhabditis elegans with 6 samples.

How the data were processed

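The binding of PHA-4 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in *Caenorhabditis elegans* of strain OP37 at the L4 larval stage, grown at 20 °C. The strain carries a transgene that expresses PHA-4 fused to GFP, and the fusion protein was precipitated with an antibody against GFP from formaldehyde-crosslinked worms, per the labels' protocols. The series holds 6 samples, which the labels divide into 3 ChIP libraries and 3 input libraries of total sonicated chromatin. Groups and replicate numbers were taken from the sample titles. The titles carry the word male, whereas the sex recorded for every sample is hermaphrodite. This conflict was not resolved. Male and hermaphrodite worms differ in their number of X chromosomes, so it bears on every value given for chromosome X.

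The values analysed were 4 lists of peaks, 1 for each ChIP replicate and 1 for the series as a whole. Peaks were called with PeakSeq on WormBase genome build WS220, per the file headers and the source field of each line. Each deposited line gives a chromosome, a start, an end and a single significance value, which has the range of a p-value, all values lying between 0 and 0.001. Whether it is a p-value or a q-value adjusted for multiple tests is not given in the sources used here, and it is called the significance value below. The authors called each replicate list on its own, and how they combined the replicates into the series-level list is not given in the sources used here. The aligner, software versions and filters are likewise not given there. The lists hold no read count, fold enrichment or strand, so the depth of each library is unknown and no value could be scaled for it. Values for the input libraries were not analysed here. Some peak numbers have no line: 93 of the 12497 numbers up to the highest in the series-level list and 4 of the 5324 in the list of replicate 1. A significance value depends on depth as well as on enrichment, so in the results it was used only to rank peaks within a list. A single test among the closing observations compares it between lists, for chromosome I against the other chromosomes, and is limited by this.

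Overlaps, merged regions and tests were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlap counts were checked against bedtools 2.31.1, which gave identical numbers in all 6 directions. Peaks were counted as shared when they overlapped by at least 1 bp. Overlapping peaks of the 3 replicate lists were merged into regions, and a region was called reproduced when it held peaks of at least 2 replicates. Chance overlap was estimated from 10000 circular shifts of a list along each chromosome, which keep widths and spacing. These permutation tests were one-sided, with Benjamini-Hochberg adjustment over the 6 directions, and the smallest p-value they can give is 1e-04. Chromosome lengths of WS220 were not used, and each chromosome was taken to end at its last peak in any list, 100.2 Mb in total. Regions per chromosome were compared with these spans by two-sided exact binomial tests, with Benjamini-Hochberg adjustment over the 6 chromosomes. The chi-square statistic over all chromosomes was compared with 10000 simulated multinomial draws of independent regions by span. The share of regions in the central 50% of each chromosome was compared with 10000 circular shifts (two-sided). Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. Runs of peaks were built by joining peaks of a list separated by at most 2 kb, and runs of at least 10 kb were listed. The runs, the central share, the spacing and the share of chromosome I were examined only after the data had been seen, as were their limits in bp. The overlap functions were tested on simulated data with the real peak numbers and widths, placed uniformly along each chromosome and with fewer shifts. In a list simulated after the 2802 peaks of replicate 2, 28.7% were replaced by copies of simulated replicate 1 peaks. The excess over shifted lists was then 28.3%. Of 20 simulations of unrelated lists, 0 gave p under 0.05 for that overlap and 1 for the count of reproduced regions. The real peaks are clustered and the simulated ones are not, so the simulations check the functions and not the error rate of the tests on the real lists.

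The design, the alternatives and the gene lists were fixed before the data were examined. The alternatives were a reciprocal overlap of 50%, midpoints within 200 bp, the better-ranked 50% of each list, lists cut to equal size, regions in all 3 replicates, and each replicate left out in turn. Tests on genes were also planned: the position of regions relative to genes, the occupancy of 25 gene lists by tissue and family, and a search for the FOX motif TRTTKRY. They were not run, since the gene table at hand refers to assembly WBcel235 and no sequence or annotation of WS220 was used here. The rule fixed for named genes (pha-4, unc-119, members of the lists by rank, and the genes nearest to the 10 strongest series-level peaks) could for this reason be applied only to the 10 peaks themselves, which are given by position.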

Results

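ChIP-seq of GFP-tagged PHA-4 was used to identify the regions of the *C. elegans* genome bound by this factor in L4 larvae. PHA-4 is the FoxA-type forkhead transcription factor of the worm and is needed to form the pharynx. The strain was made in an unc-119 mutant background, and its transgene carries both the tagged pha-4 gene and an unc-119 rescue. The data comprised 3 ChIP libraries, each with its own peak list, 3 input libraries whose values were not analysed here, and 1 series-level list. The ChIP libraries form a single group, so the comparisons that the design allows are among replicates, among chromosomes and among regions. The labels do not say whether the replicates came from separate cultures, so differences between them may be technical. The p-values below measure departure from random placement or counting error in these samples, not variation between cultures. The replicate lists held 5320, 2802 and 1900 peaks for replicates 1, 2 and 3, or 3341 ± 1772 (SD, n = 3), a 2.8-fold range. The series-level list held 12404 peaks. Peaks had a median width of 375, 445 and 459.5 bp in replicates 1, 2 and 3, or 426.5 ± 45.2 bp (SD, n = 3), and 327 bp in the series-level list. They covered 2.46%, 1.54% and 1.08% of the genome span in the replicates and 5.36% in the series-level list. Depth was unknown, so the differences in peak number could not be set against sequencing depth. No pair of replicates had more than 1 peak with the same start and end.

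The 10 strongest PHA-4 regions of the series-level list were called in all 3 replicates. They are the peaks with the lowest significance values and lay on chromosomes V, X, I and II (build WS220). These values are the authors' own and serve here to rank peaks within a list. The first was a domain of 34296 bp on chromosome V, from 20740334 to 20774629, whose significance value is listed as 0. Its best peak ranked 4 in replicate 1, 2 in replicate 2 and 3 in replicate 3. Extra copies of the tagged transgene were considered for this domain among the closing observations and stay open, so it may not reflect binding alone. The second, on chromosome X from 16929196 to 16932046 (significance value 3.17e-278), ranked 3, 3 and 4. The third, on chromosome I from 7078953 to 7085199 (significance value 2.3e-263), ranked 5, 6 and 10. Chromosome V held 3 more of the 10. The region from 723595 to 731741 ranked 42, 5 and 6 in replicates 1, 2 and 3. Adjoining regions from 6220678 to 6225760 and from 6225962 to 6231131 ranked 7, 4 and 5, and 17, 7 and 5. The rank of 5 in replicate 3 is that of a single peak, from 6222398 to 6226500, which overlaps both regions. Chromosome II held a pair of adjoining regions, from 10541854 to 10547008 (ranks 14, 9 and 8) and from 10547598 to 10554892 (ranks 85, 13 and 79), and a region from 9616848 to 9622312 (ranks 27, 14 and 31). The last of the 10 lay on chromosome I from 7656304 to 7660498 and ranked 13, 16 and 17. Genes at these positions were not assigned.

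Other strong regions, singled out after their values were seen, were not called in every list. A region on chromosome IV from 11694635 to 11700624, which ranked 11 in the series-level list (significance value 5.9e-148), ranked 8 in replicate 2 and 2 in replicate 3 but overlapped 0 peaks of replicate 1. Of the 300 best series-level peaks, 2 were not called in replicate 1, 7 in replicate 2 and 10 in replicate 3. The other one missing from replicate 1 lay on chromosome IV from 10089824 to 10090694 and ranked 225. A stretch on chromosome III, described with the runs of peaks, supplied 5 of those missing from replicate 2 and 5 of those missing from replicate 3. The first-ranked peak of each replicate list lay near the end of chromosome I, between 15063992 and 15067641, was 3647, 3618 and 3637 bp wide in replicates 1, 2 and 3, and had a value listed as 0. The series-level list holds 0 peaks there, and its last peak on chromosome I ends at 14953515.

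The replicate lists overlapped far more than shifted lists did. Of the peaks of replicate 3, 76.1% (95% interval 74.1 to 78%) overlapped a peak of replicate 1 and 64.4% (62.2 to 66.5%) a peak of replicate 2. Of the peaks of replicate 2, 68.6% (66.8 to 70.3%) overlapped replicate 1 and 43.9% (42 to 45.7%) replicate 3. The longer list of replicate 1 was found in replicates 2 and 3 for 36% (34.7 to 37.3%) and 27.2% (26 to 28.5%) of its peaks. Shifted lists gave means of 1.99 to 5.49%, so the overlaps were 12.6 to 20.2 times chance, and in all 6 directions the permutation p was 1e-04 before and after Benjamini-Hochberg adjustment, the smallest value possible. With each list cut to its 1900 best peaks, the 6 overlaps ranged from 53.4 to 55.7%. Better-ranked peaks were shared more often. Of the 100 best peaks, 91 in replicate 1, 97 in replicate 2 and 98 in replicate 3 were called in both other replicates, against 18, 67 and 165 of the worst 500. Across shared peaks, Spearman's rho of the significance ranks, by definition Pearson's r of the ranks, was 0.45 between replicates 1 and 2, 0.52 between 1 and 3 and 0.50 between 2 and 3. Peaks are not independent replicates, so no p is given.

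Merging the 3 lists gave 6420 regions, of which 2301 (35.8%, 95% interval 34.7 to 37.0%) were reproduced, that is, called in at least 2 replicates. In all 3 replicates 1059 regions were called. Shifted lists gave a mean of 301 regions in at least 2 lists, with a highest value of 575, and a mean of 5.65 in all 3, with a highest value of 26 (permutation p = 1e-04 for both, the smallest possible). Regions called in 1 replicate numbered 4119, of which 3044 came from replicate 1, 750 from replicate 2 and 325 from replicate 3. Reproduced regions had a median width of 646 bp, those in all 3 replicates 782 bp and those in 1 replicate 327 bp, a contrast that follows in part from merging overlapping peaks. With only 2 lists left the count falls by construction: 1186 regions were shared without replicate 1 and 1408 without replicate 2.

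The series-level list extended well beyond the peaks of the replicates. Of its 12404 peaks, 6655 (53.7%, 95% interval 52.8 to 54.5%) overlapped no replicate peak, 3463 overlapped peaks of 1 replicate, 1231 of 2 and 1055 of all 3. The share overlapped by at least 1 replicate fell from 46.3% to 25.8% without replicate 1, and that by at least 2 from 18.4% to 9.36% without replicate 1 and 11.2% without replicate 2, in part because fewer lists were left. Support fell steeply with rank. In the first decile, 95.2% of peaks were overlapped by at least 2 replicates and 4 of 1240 by none, whereas in the last decile 93.2% were overlapped by none. The median width fell from 955 bp in the first decile to 155 bp in the last. The highest-ranked peak without replicate support lay on chromosome V from 10470626 to 10473025 and ranked 824. In the other direction, 92.2% of replicate 1, 97.5% of replicate 2 and 98.5% of replicate 3 lay in the series-level list. Whether the series-level peaks were called on the replicates' pooled reads is not given in the sources used here, so this overlap is not taken as independent evidence. In the series-level list, 466 peaks (3.76%) were under 20 bp wide, against 50, 0 and 1 in replicates 1, 2 and 3.

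**Figure D1:**
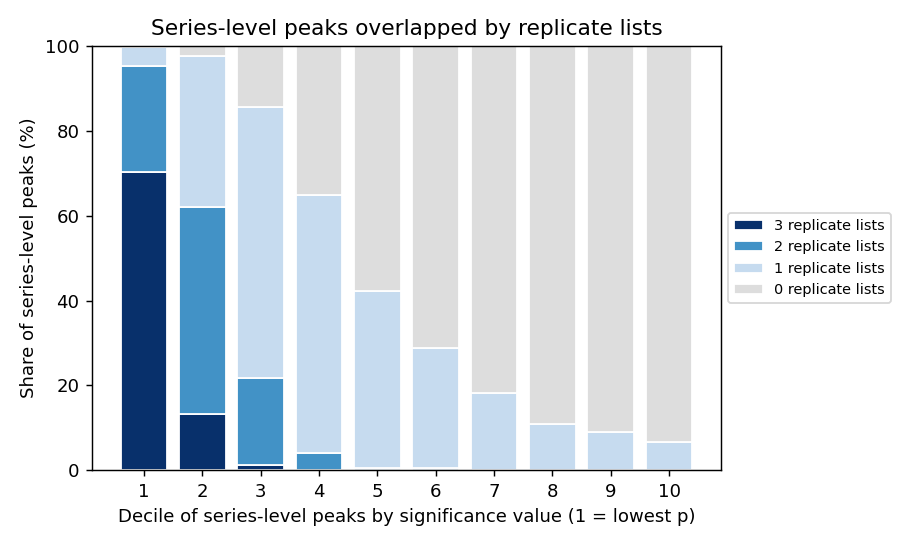
Share of series-level peaks (%, vertical axis) overlapped by 3, 2, 1 or 0 of the replicate peak lists, for deciles of the series-level list by significance value (horizontal axis, 1 holds the lowest significance values, which the axis label calls p). Overlap by at least 2 lists falls from 95.2% in the first decile to 0 in the last 4 deciles.

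Reproduced PHA-4 regions were densest on chromosome III and sparsest on chromosome V. Chromosome III held 453 of 2301 regions, 32.9 per Mb and 1.43 times the number expected from its span (exact binomial test, adjusted p = 1.1e-14). Chromosome V held 326, 15.6 per Mb and 0.68 times expectation (exact binomial test, adjusted p = 1.1e-15). Both directions held in each replicate list: chromosome III held 19.7 ± 0.68% of the peaks (SD, n = 3) on 13.7% of the span, and chromosome V 14.2 ± 0.036% on 20.9%. Chromosome IV was above expectation (25.4 per Mb, 1.11 times, exact binomial test, adjusted p = 0.032). That call was lost in regions of all 3 replicates, in the lists of replicates 1 and 3, and without replicate 2, where the ratios were 1.14, 1.05, 1.11 and 1.07 (exact binomial tests, adjusted p = 0.064, 0.12, 0.051 and 0.31). Chromosomes II (24.7 per Mb, 1.08 times, adjusted p = 0.16) and X (23 per Mb, 1.0 times, adjusted p = 0.98) did not pass the exact binomial test. Chromosome X was below expectation, however, in the list of replicate 1 (0.87 times, adjusted p = 1.0e-05) and in the series-level list (0.89 times, adjusted p = 3.1e-09) by the same exact test. The unresolved sex label bears on these values. Over all chromosomes the distribution departed from the spans (chi-square against simulated multinomial draws, p = 1e-04, the smallest possible). Neighbouring regions are not independent, and both the binomial test and the simulated draws treat them as if they were.

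Chromosome I differed between replicates. Reproduced regions there numbered 294, 19.5 per Mb and 0.85 times expectation (exact binomial test, adjusted p = 0.0044). The list of replicate 1, however, had 17.7% of its peaks on chromosome I (95% interval 16.6 to 18.7%), above the 15% of the span, while replicates 2 and 3 had 11.3% (10.2 to 12.6%) and 11.5% (10.1 to 13%). Fisher's exact test (two-sided) gave an adjusted p of 8.6e-14 for replicate 1 against 2, 2.5e-10 for 1 against 3 and 0.85 for 2 against 3. These tests compare libraries, not conditions. The direction for chromosome I therefore depends on the list, being 1.17 times expectation in replicate 1 and also in the series-level list.

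**Figure D2:**
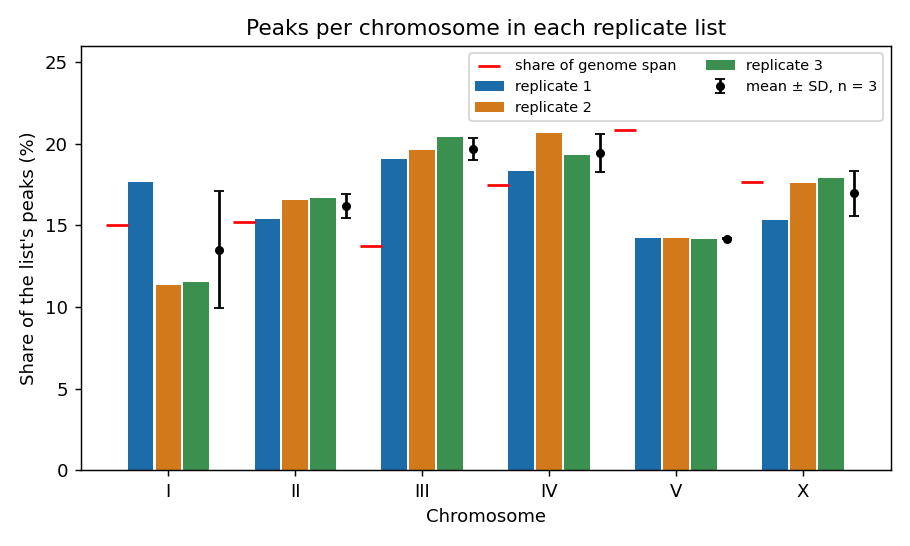
Share of each replicate list's peaks (%, vertical axis) on each chromosome (horizontal axis), with the mean ± SD of the 3 replicates as points and the chromosome's share of the genome span as red lines. Chromosome III lies above and chromosome V below its span in every replicate, while chromosome I is 17.7% in replicate 1 and 11.3 and 11.5% in replicates 2 and 3.

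The central 50% of the chromosome span held 66.0% of the reproduced regions on chromosome I, 61.0% on II, 60.7% on III, 61.0% on IV, 65.3% on V and 50.9% on X. No single chromosome passed the circular-shift test after adjustment over the 6 chromosomes (permutation test, adjusted p from 0.18 to 0.72), the lowest unadjusted p being 0.030 for chromosome III. Over all 6 chromosomes together, 1390 of 2301 regions were central (60.4%, 95% interval 58.4 to 62.4%), against a mean of 50.05% in shifted regions. The permutation p of 0.00080 for this share comes from a test added after the shares per chromosome were seen, so it is not independent evidence of a central excess. The same share was 57.4, 58.2 and 59.8% in the lists of replicates 1, 2 and 3, from which the reproduced regions were made, and 55.2% in the series-level list. The difference between the X chromosome and the autosomes was not tested. Reproduced regions also lay close to one another. Midpoints of 268 neighbouring pairs were within 2 kb, against a mean of 108 and a maximum of 136 in 1000 uniform placements (permutation p = 0.001, the smallest possible), and the median gap between neighbours was 17.8 kb. Uniform placement takes no account of uneven density along the chromosomes or of a broad domain split into several peaks. The p therefore measures departure from uniform placement only.

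Runs of closely spaced peaks at least 10 kb long numbered 69 in the series-level list, on all 6 chromosomes, and 14, 4 and 3 in replicates 1, 2 and 3. The longest run of the series-level list covered 37.9 kb of chromosome V, from 20740334 to 20778235, and included the first-ranked peak. Peaks covered 77% of it in replicate 1, 65.7% in replicate 2 and 57.8% in replicate 3, and the widest single peak of each replicate list lay in it, at 12909, 19846 and 12789 bp. The next, on chromosome IV from 3846804 to 3878787 (32.0 kb), was covered for 25.3, 42.9 and 47.1% in replicates 1, 2 and 3. A run on chromosome III from 7524670 to 7554569 (29.9 kb) was called in replicate 1 and in the series-level list, where 22 peaks covered 59.2% of it. In replicate 1, a total of 16 peaks covered 77.5% of it, 7 of them among the 100 best of that replicate and the best with rank 2 (significance value 5.1e-139), whereas replicates 2 and 3 had 0 peaks in it. None of these 7 peaks overlapped a peak of replicate 2 or 3, against 93 of the other 93 among the 100 best (95% interval 96.1 to 100%). The stretch was picked because it was called in replicate 1 alone, so no p is given for this difference.

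**Figure D3:**
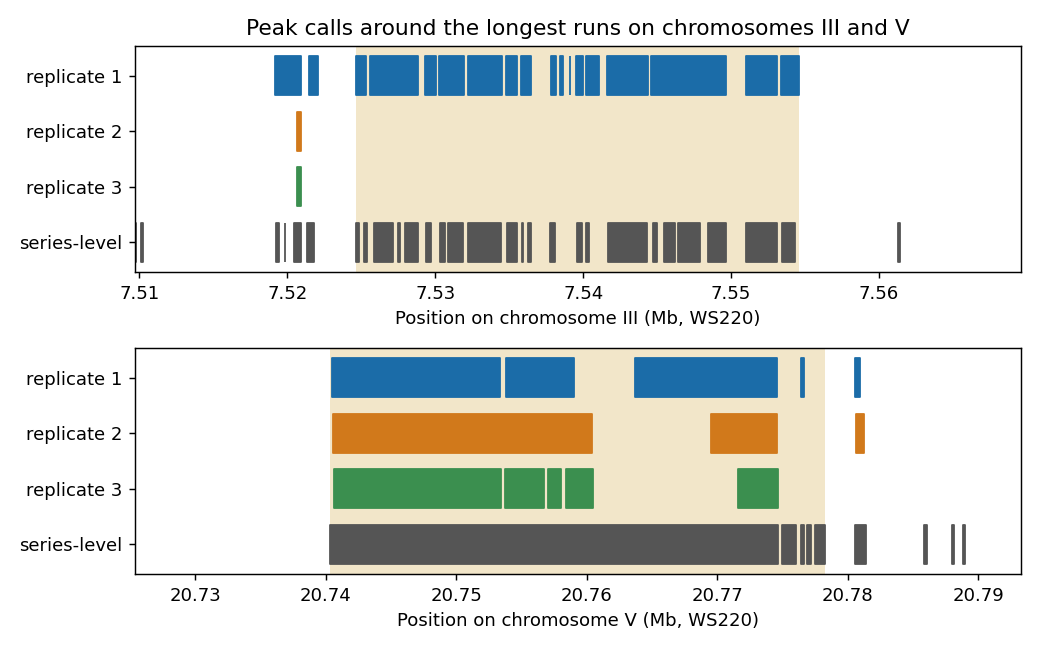
Peaks of each replicate and of the series-level list (bars, drawn to scale, in 4 rows) along chromosome III (upper panel) and chromosome V (lower panel), positions in Mb of build WS220, with the runs of 29.9 and 37.9 kb shaded. The shaded stretch of chromosome III holds 16 peaks in replicate 1 and 0 in replicates 2 and 3, while that of chromosome V is covered in all 3 replicates.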

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

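All 6 pairwise overlaps stayed above chance under the 5 alternatives tried, of which leaving out chromosome I was chosen after seeing the data (30 of 30 values, permutation p = 0.001 with 1000 shifts, the smallest possible). Their size moved most for replicate 1 in replicate 3, between 21.2 and 54.2%. The count of 2301 reproduced regions fell to 1059 when all 3 replicates were required and to 1167 with the better-ranked 50% of each list, both by construction, and ranged from 1186 (without replicate 1) to 1855 with 1 replicate left out. It stayed within 1.5 times under a reciprocal overlap of 50% and, an alternative added later, without the runs on chromosomes III and V and the end of chromosome I. In the better-ranked 50% of each list the median width rose to 505, 586 and 590.5 bp in replicates 1, 2 and 3 and to 489 bp in the series-level list. With a reciprocal overlap of 50%, replicate lists reached 38.9% of series-level peaks (at least 1 replicate) and 12.9% (at least 2), against 46.3 and 18.4%, and rho rose to 0.58, 0.64 and 0.62 for replicates 1 and 2, 1 and 3, and 2 and 3. The cause was not tested. With 1 replicate left out, added later, these shares ranged from 25.8 to 44.1% and from 9.36 to 14.9%, the lowest without replicate 1. The uneven distribution over chromosomes held under all 9 alternatives. Single chromosomes changed direction in 7 of 54 values. Chromosome I went to 1.17 times expectation in the list of replicate 1 and in the series-level list. Chromosome X went to 0.87 (replicate 1), 0.998 (replicate 2), 0.89 (series level) and 0.997 (without replicate 3, the lowest with 1 replicate left out, the highest being 1.03 without replicate 2), and chromosome II to 0.997 (series level). The central share on X went to 49.2% in replicate 2 and 47.2% in regions of all 3 replicates, neither of which passed the test. Expectation by gene number was not run, so the chromosome ratios rest on span alone. The location and promoter tests and the motif search were not run, for want of an annotation or sequence of build WS220. No paired analysis was possible because no values of the input libraries were analysed here, and the ChIP libraries form 1 group. Library depth, which the lists do not give, limits every comparison of list sizes.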

Other observations

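All tests below were chosen after the patterns had been seen. The outcome each explanation would give was written down before the result only for the test of shifted significance values on chromosome I.

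The smaller share of chromosome I in replicates 2 and 3 does not follow from their shorter lists, since 17.1% of the 1900 best peaks of replicate 1 lay on chromosome I, above the upper bounds of 12.6 and 13% in replicates 2 and 3. Replicate 2 recovered 16%, 31.4% and 27.4% of the peaks of replicate 1 in 3 equal segments of chromosome I. Each had an upper bound below the 38.5% (95% interval 37.0 to 39.9%) elsewhere. Low recovery by replicate 2 was therefore not confined to a single segment. Replicate 3 recovered 11%, 25.6% and 20%, against 29.1% (27.7 to 30.4%) elsewhere. The interval of its middle segment (21.1 to 30.4%) overlapped that range. In both replicates recovery was lowest in the first segment, whose interval lay below those of the middle and last segments. Recovery does not separate calls lost in replicates 2 and 3 from calls added in replicate 1. For replicate 2, the outcome written down against a loss in 1 part was met, since all 3 segments lay below 37.0%. That outcome was written after the result, and it does not exclude a stronger loss in the first segment. Loss of calls in a part of chromosome I therefore stays open for both replicates. In regions called in all 3 replicates, log10 significance values relative to replicate 1 were weaker on chromosome I than elsewhere. The difference was 1.64 in replicate 2 (permutation p = 0.00080) and 0.81 in replicate 3 (permutation p = 0.058). Median shifts of the other single chromosomes ranged from 0.81 to 1.77 in replicate 2, against 2.99 on chromosome I. In replicate 3 they ranged from 1.82 to 2.80, against 3.18. The p-values do not measure this spread between chromosomes. Values of lists of unknown depth are not on a common scale, so a chromosome-wide shift of the values and a difference in binding cannot be told apart. No biological explanation was tested, since the labels name no difference between the replicates.

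The run of 29.9 kb on chromosome III in replicate 1 does not follow from the shorter lists of replicates 2 and 3, since 100% of the other 93 peaks among its 100 best were found in replicate 2 or 3. Extra DNA of this stretch in the replicate 1 library may account for it, as a hypothesis: peaks covered 77.5% of it there, in 16 peaks, whereas the 37.9 kb run on chromosome V was held by 4 peaks in that replicate, and peak coverage does not separate extra DNA from binding. The input of replicate 1 was not analysed here, so this stays open. Together with the larger share of chromosome I, the run raises the doubt whether replicate 1 came from the same strain or construct as the others. This is a hypothesis that was not tested. Replicate 1 also lacks the region on chromosome IV from 11694635 to 11700624, although each list missed some of the 300 best series-level peaks. Outside the stretch on chromosome III, 2, 2 and 5 of the 300 best series-level peaks were missing from replicates 1, 2 and 3. The region on chromosome IV ranked highest of these, at 11. Of the 100 best peaks of replicate 1, 91 were called in both other replicates. No biological explanation was tested.

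Outside this stretch, 3 of the 300 best peaks of replicate 1 were absent from both other replicates (chromosome I from 2935441 to 2936381 and from 170000 to 171577, and chromosome IV from 9875369 to 9876516). Of the 300 best of replicates 2 and 3, 0 were private to 1 replicate. The peaks of replicate 1 were sought in lists of 2802 and 1900 peaks. Those of replicates 2 and 3 were also sought in its list of 5320 peaks, so part of this difference is built in.

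Extra copies of the tagged transgene were considered for the run on chromosome V, as the transgene carries the pha-4 gene. The outcome written down for that cause was a run longer than every other in each of the 3 replicate lists that overlaps pha-4, and the outcome against it a run that was not the longest in at least 2 of them. The run was the longest in 1 of the 3, and the widest single peak lay in it in 3 of 3. The outcome against it was wrongly chosen, because extra copies at a single place do not limit runs elsewhere, so it excludes nothing. The position of pha-4 in build WS220 was not used here, so the explanation stays open, and no biological explanation was tested.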
